A study of Mus musculus with 24 samples.

How the data were processed

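Gene expression was measured in whole spleen of 4 female and 4 male BWF1 mice, the lupus-prone F1 hybrids of the New Zealand Black and New Zealand White strains, at an age of 4 months and before disease. Each mouse was measured on the 3 Affymetrix chips of the murine U74 set (A, B and C), which gave 24 arrays. Per the labels, total RNA was copied to double-stranded cDNA from an oligo(dT) primer carrying a T7 promoter, and biotin-labelled cRNA was transcribed from it. Arrays were grouped by the sex and mouse number in their titles, and no array was left out. The array information files gave chip type, fluidics station, module and time of the run, and were used only to look for batches.

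The values are linear probe set signal intensities as deposited by the authors, with 1 value per probe set and array. They had been scaled by the authors: the mean after trimming 2% at each end lay between 500.1 and 500.3 on each of the 24 arrays. The summary software and its version are not given in the sources used here, and no detection calls accompany the values. Cell-level image data were not analysed here.

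The values were used as deposited. Signals under the 20th percentile of the chip (33.98 on chip A, 63.40 on chip B, 54.93 on chip C) were set to that floor, and log2 was taken. A difference of log2 means between a group at the floor and another group is therefore a lower bound. Control probe sets (66 per chip) were removed, and probe sets were kept when their mean log2 signal over the 8 arrays was at or above the median of the chip, which left 6211, 6206 and 5934 probe sets on chips A, B and C. The platform annotation assigned 29131 of the 36701 non-control probe sets to 1 gene, 724 to several genes and 6846 to none.

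Females and males were compared within each chip with limma 3.58.1 in R 4.3.3 (sex as the only term, moderated variances with a trend in signal level, two-sided). Differences are female minus male on the log2 scale with the moderated standard error (SE). P values were adjusted by the Benjamini-Hochberg method within the chip, and a probe set passed at an adjusted p under 0.05. For values per mouse, such as list scores, an exact two-sided permutation test over all assignments of 8 mice to groups of 4 was used, whose smallest possible p is 0.0286.

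For gene lists, 10376 genes were represented by 1 probe set each: the brightest one that is assigned to the gene alone and passes the filter, on the lowest-lettered chip that has one. The 3 chips were joined by mouse number, taken to be the same mouse on each chip. Departures from the mean of the sex correlated best with the same number, among all 8 mice, in 8 of 8 mice between chips A and B and in 4 of 8 between A and C and between B and C. Among mice of the same sex the counts were 8, 6 and 6 of 8, so that the join is less certain for chip C. The 29 lists covered cell types of the spleen and of neighbouring tissue, sex chromosome genes, responses to interferon and to steroid hormones, and lupus-associated and other immune genes; 28 had enough measured members to be tested. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. Members were counted as passing over all genes tested and adjusted over the list alone. A list score is the mean over members of the log2 signal centred on the 8 mice.

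The lists, filters, tests and alternatives were fixed before the data were examined. So was the rule for named genes: Xist and the Y-linked genes; in each direction the 12 genes with the largest difference among those passing with no overlap between the sexes, or, where fewer than 8 pass, those that pass followed by the genes of smallest p up to 8; and from each list up to 4 members that pass, or the 2 of smallest p as values. Genes named outside that rule are said to have been chosen after their values were seen.

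The alternatives changed one choice at a time: quantile or median scaling, the floor (at the 10th percentile, or absent), the filter (absent, or at the 75th percentile), the variance model, array weights, adjustment over the 3 chips together, the mouse number or the fluidics module as a block, an unmoderated test, chip A alone or the mean of all probe sets for the lists, and each mouse left out in turn. The pipeline was tested on simulated data with 4 arrays per group and 100 probe sets changed at each of 2 sizes. It recovered 69%, 72% and 23% of true 2-fold changes on chips A, B and C, and 98%, 100% and 78% of true 4-fold changes. False calls made up 2.34%, 6.01% and 5.61% of those made. These shares hold for that number of changed probe sets. With fewer changed, the adjustment is stricter and recovery may be lower. The number of arrays limits the precision. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.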

Results

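Spleen RNA from 4 female and 4 male BWF1 mice aged 4 months was profiled on 24 arrays, 3 per mouse. Per the labels, the purpose was to find immune genes that differ between the sexes before lupus begins, including genes under sex hormone control, since females of this hybrid develop the disease more often. Median signal per array was 193 to 214 on chip A, 260 to 282 on chip B and 213 to 232 on chip C. The ratio of 3′ to 5′ probe set signal ranged from 1.02 to 1.19 for Actb and from 0.857 to 1.12 for Gapdh. On chip B the Actb ratio was 1.12 to 1.15 in females and 1.07 to 1.10 in males. The sexes overlapped in the other pairs of gene and chip. All female arrays were washed on one fluidics station and all male arrays on another, so that station and sex cannot be told apart in any comparison. The chip A array of female 2 was run 8 days after the other chip A arrays.

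Among named genes that passed, the largest differences between female and male spleens were in Xist and Kdm5d, on the X and Y chromosomes. Xist, the X-linked noncoding RNA that silences an X chromosome in female cells, was higher in females by 4.94 ± 0.28 (SE) on the log2 scale (chip A), at least 30.7-fold since 2 of 4 males were at the floor (limma adjusted p = 7.73e-06). Mean log2 signal was 10.38 ± 0.44 in females and 5.44 ± 0.48 in males (SD, n = 4 each). Kdm5d, a histone demethylase gene of the Y chromosome, was lower in females by at least 12.2-fold (chip B, −3.61 ± 0.31, adjusted p = 6.93e-05), with 3 of 4 females at the floor. Of the X-linked genes outside the inactivation centre, Kdm6a, which encodes a histone demethylase, was 2.59-fold higher in females (chip A, 1.37 ± 0.18, adjusted p = 0.0295). Nono, an X-linked gene for an RNA- and DNA-binding protein of nuclear paraspeckles, was higher in females on 2 chips, by 1.66 ± 0.18 on chip C (adjusted p = 0.00361) and 0.98 ± 0.14 on chip A (adjusted p = 0.0401).

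The remaining differences that passed were all lower in females. A probe set of a variable gene segment of the immunoglobulin kappa light chain, encoded on chromosome 6, was 3.27-fold lower (chip A, −1.71 ± 0.26, adjusted p = 0.0401), with mean log2 signals of 11.14 ± 0.59 in females and 12.85 ± 0.30 in males (SD, n = 4 each). A chip B probe set that has no gene name in the annotation read 2.37 to 4.53 in females and 2100 to 2776 in males, a difference of at least 37.1-fold (adjusted p = 2.68e-09). A further unnamed probe set, on chip A, was 2.73-fold lower (−1.45 ± 0.22, adjusted p = 0.0401). These 3 probe sets, and the chip C probe set of Nono, lie outside the rule for named genes and were chosen after their values were seen.

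In all, 8 of 18351 probe sets passed, 4 higher and 4 lower in females: 5 of 6211 on chip A, 2 of 6206 on chip B and 1 of 5934 on chip C. At an unadjusted p under 0.05 there were 650, 577 and 360, against 310.6, 310.3 and 296.7 for uniform p values, and 4, 4 and 6 of the 35 splits of the mice into groups of 4 gave as many. The sexes did not overlap in any of the 8. Single mice decided the chip A and B counts: without female 1 they were 43 and 29, all calls of the full data included, and chip A gave 1 without female 2, male 1, male 2 or male 4 and 2 without female 3 or male 3. Chip C gave 2 without female 1 or male 2. Under other limma settings the calls of Kdm6a, Nono on chip A, the unnamed chip A probe set and the kappa segment ended with adjusted p up to 0.205, 0.179, 0.349 and 0.349, while that of Nono on chip C ended without the variance trend (adjusted p = 0.126, the highest over its alternatives), and those of Xist, Kdm5d and the unnamed chip B probe set held in each limma setting whose filter kept them.

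**Figure D1:**
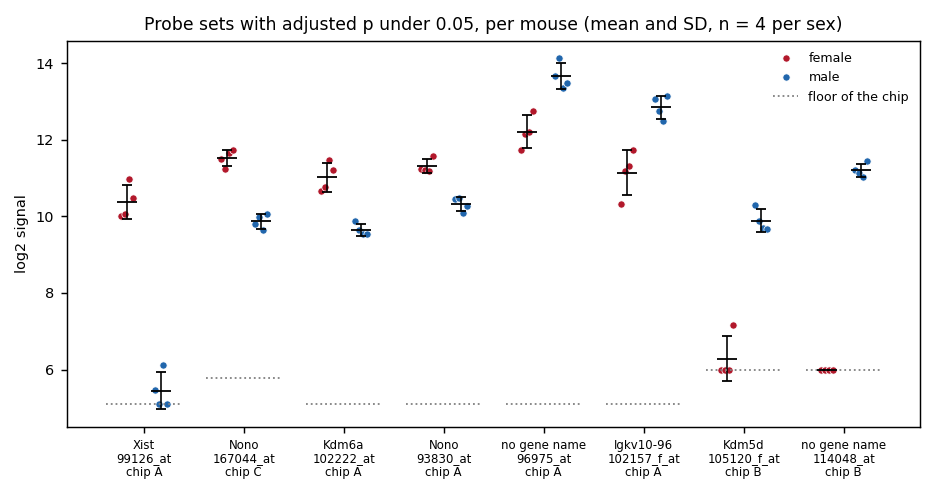
Log2 signal of each mouse for the 8 probe sets with an adjusted p under 0.05, females in red and males in blue, with bars for the mean and SD of 4 mice and dotted lines for the floor of the chip. Females and males do not overlap in any of them. All 4 females lie at the floor for the unnamed chip B probe set, and 3 of 4 for Kdm5d.

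Dimmer probe sets of sex chromosome genes, under the level filter, separated the sexes in the same direction. Eif2s3y, a Y-linked translation initiation factor gene, read 3.24 to 61.4 in females and 516 to 680 in males (chip A, exact permutation p = 0.0286, the smallest possible). Uty (−1.79), dimmer probe sets of Kdm5d on chips A (−1.06) and B (−1.86) and a chip B probe set of Xist (1.37) each had the same exact p. Sry and Uba1y read near the floor in both sexes. All 8 mice matched the sex of their labels in Xist, Eif2s3y and Kdm5d.

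Of the 9 measured genes in the list of X-linked inactivation and escape genes, Xist and Kdm6a were higher in females over all genes tested. Adjusted over the list alone there were 3, with Eif2s3x, the X-linked partner of Eif2s3y, at 0.57 ± 0.11 (adjusted p = 0.155 over all genes). The list was higher in females (camera adjusted p = 5.51e-05; adjusted p = 0.0985 with an estimated correlation), with a score of 0.39 ± 0.16 in females and −0.39 ± 0.05 in males (SD, n = 4 each; exact p = 0.0286); on chip A alone the difference of 0.78 was 1.44. Some probe sets of the same genes differed little: another chip A probe set of Nono gave 0.24 ± 0.27 and the chip C probe set of Kdm6a gave −0.01 ± 0.40. A chip B probe set of Kdm6a gave 1.10 ± 0.16 with no overlap of the sexes but did not pass (limma adjusted p = 0.250). The SE of these probe sets of Nono and Kdm6a come from a fit to all probe sets of the chip, without the level filter. The adjusted p comes from the filtered fit. Of the list, 7 members were higher and 2 lower in females, with a median of 0.23, and the mean of 0.78 owes most to Xist. The other 6 members, named after their values were seen, did not pass with the probe set that represents them: Mid1 (0.38), Usp9x (0.23), 5530601H04Rik (0.18), Ddx3x (0.10), Kdm5c (−0.09) and Jpx (−0.67 ± 0.62). Kdm5c had 3 other probe sets, at 0.50, 0.85 and 1.41, and the sexes did not overlap in the last, which lay under the level filter. The Y-linked list had 1 member above the filter, Kdm5d.

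Immunoglobulin genes leaned lower in females, with large differences between individual mice. Of 49 immunoglobulin probe sets, 35 were lower and 14 higher in females, with a median of −0.33, which was −0.12 without female 1. A score over all 25 immunoglobulin genes, a set taken after the values were seen, differed by −0.41 (exact p = 0.114; unadjusted camera p = 1.34e-06, and p = 0.168 with an estimated correlation). At an unadjusted p under 0.05 there were 16 lower and 0 higher, and 1 passed with limma, the kappa segment probe set above. The brightest probe set of that kappa segment differed by −1.51 ± 0.29 (adjusted p = 0.145). Igha, the constant region of the IgA heavy chain, differed by −1.36 ± 0.30 (adjusted p = 0.202), and 1 of its 3 probe sets was higher in females (0.13). The fixed list of immunoglobulin transcripts had 8 measured members, 6 lower and 2 higher in females. Over all genes tested 0 passed with limma, 2 had an unadjusted p under 0.05, and adjusted over the list alone 1 passed, Igha (camera adjusted p = 0.0900). Ighg3, the constant region of an IgG heavy chain, differed by −0.55 ± 0.21 with its brightest probe set, but 4 of its 6 probe sets were higher in females (0.08 to 0.23). The list passed without female 4 (−0.31) or male 3 (−0.32), against −0.22 with all mice, and stood at −0.14 without female 2, −0.11 without the filter and −0.10 with the mean of all probe sets of a gene. Female 1 lay lowest, with a median of −0.99 over the 49 probe sets relative to the median mouse, against −0.43 to 0.10 in the other females and −0.07 to 0.38 in the males.

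**Figure D2:**
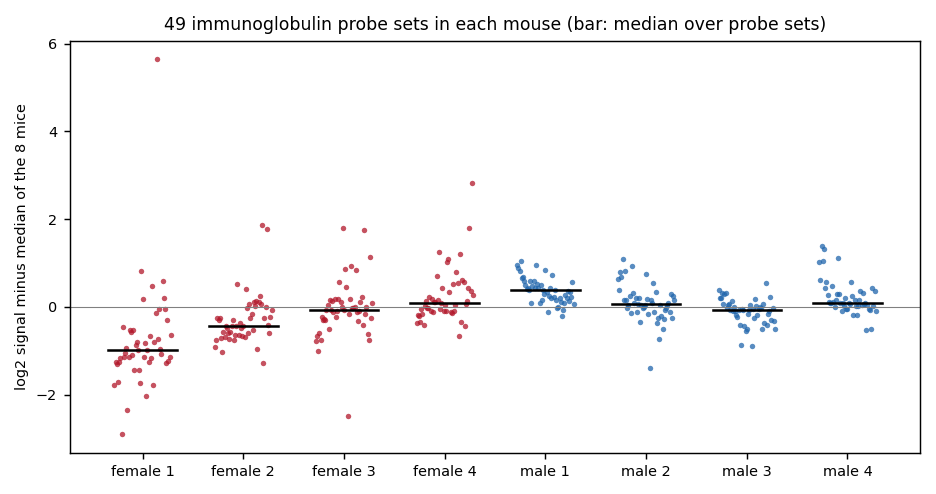
Log2 signal of 49 immunoglobulin probe sets in each mouse, minus the median of the 8 mice for that probe set, with 1 point per probe set and a bar at the median of the mouse. Female 1 has the lowest median, −0.99, and also the highest single point, 5.64.

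Markers of B cells did not pass as a list. Of 28 measured B cell markers 17 were lower and 11 higher in females (score −0.16, camera adjusted p = 0.0848). None passed with limma over all genes tested, 5 had an unadjusted p under 0.05, all lower, and adjusted over the list alone 1 passed, Fcer2a. Fcer2a, the low-affinity IgE receptor of B cells, differed by −1.02 ± 0.19 (adjusted p = 0.124). Bcl11a, a transcription factor of the B lineage, differed by −0.45 ± 0.15, with 2 of its 3 probe sets in that direction. The list passed in 4 of 14 alternatives (adjusted p from 0.00470 to 0.743): with the mean of all probe sets of a gene and without female 4 (−0.17), male 3 (−0.22) or male 4 (−0.18). Without male 1 the difference was −0.08.

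Genes of plasma cells and antibody secretion were higher in females as a list, in the opposite direction to the immunoglobulin probe sets. Of 29 measured members 25 were higher and 4 lower (camera adjusted p = 3.66e-05; adjusted p = 0.633 with an estimated correlation). Over all genes tested 0 passed with limma and 6 had an unadjusted p under 0.05. Adjusted over the list alone 5 passed: Pdia6, a disulfide isomerase of the endoplasmic reticulum (0.59 ± 0.14), and Tnfrsf17, a survival receptor of plasma cells (0.61 ± 0.16), and, chosen after their values were seen, Dnajb9, Prdm1 and Fkbp11. The score was 0.13 ± 0.32 in females and −0.13 ± 0.12 in males (SD, n = 4 each; exact p = 0.171). Female 1 had the highest score, 0.56, and without it the difference of 0.26 was 0.11 and the list no longer passed.

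Megakaryocyte and platelet genes were higher in females. Of 17 measured members 15 were higher and 2 lower, with a score of 0.24 ± 0.44 in females and −0.24 ± 0.24 in males (SD, n = 4 each; exact p = 0.0857; camera adjusted p = 2.80e-06; adjusted p = 0.633 with an estimated correlation). Over all genes tested 0 passed with limma and 6 had an unadjusted p under 0.05, all higher. Adjusted over the list alone 5 passed: Gp9, a subunit of the platelet receptor for von Willebrand factor (0.84 ± 0.19), and F2rl2, a receptor of the thrombin family (0.83 ± 0.18), and, chosen after their values were seen, Gp1bb, Clec1b and Alox12. Female 2 had the highest score, 0.87, and without it the difference of 0.49 was 0.28, and the list still passed. Its chip A array, the chip of 11 of the 17 members, was run 8 days after the other arrays of that chip.

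Genes of smooth muscle and fibroblasts, which build the capsule and trabeculae of the spleen, were lower in females. Of 22 measured members 18 were lower and 4 higher (score difference −0.31, exact p = 0.0286; camera adjusted p = 3.20e-05; adjusted p = 0.385 with an estimated correlation). Over all genes tested 0 passed with limma, and adjusted over the list alone 9 passed, the same number as had an unadjusted p under 0.05. Sparc, a collagen-binding matrix protein, differed by −0.66 ± 0.14 and elastin (Eln) by −0.71 ± 0.16. Fry's test of genes changing in either direction gave a mixed adjusted p = 0.00683. Its test of a shift in 1 direction did not pass here (adjusted p = 0.158) or for the megakaryocyte, plasma cell, cell cycle, MHC class II, endothelial and glucocorticoid lists (adjusted p = 0.434, 0.459, 0.679, 0.476, 0.459 and 0.353), nor did its mixed test for these 6. For the X-linked list both passed (adjusted p = 0.000696 in 1 direction). Endothelial genes were also lower as a list, 12 of 16 members (score difference −0.21, exact p = 0.171; camera adjusted p = 0.0118; adjusted p = 0.633 with an estimated correlation). The endothelial genes Eng, a receptor for transforming growth factor beta, and Plvap, a protein of endothelial fenestrae, differed by −0.59 ± 0.17 and −0.56 ± 0.18. For Plvap 2 of 3 probe sets went in that direction. Of the endothelial members 0 passed with limma, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. The endothelial list no longer passed without female 3 (−0.15), without female 4 (−0.15) or without the filter on dim probe sets (−0.14).

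MHC class II antigen presentation genes and glucocorticoid-responsive genes were lower in females as lists, and cell cycle genes were higher. In the MHC class II list 15 of 16 members were lower (score difference −0.20, camera adjusted p = 0.00468; adjusted p = 0.633 with an estimated correlation), with H2-DMb1 (−0.63 ± 0.19) and H2-DMb2 (−0.78 ± 0.24), subunits of the chaperone that loads peptides on class II molecules. In the glucocorticoid-responsive list 12 of 14 members were lower (score difference −0.22, camera adjusted p = 0.0182; adjusted p = 0.633 with an estimated correlation), with the glucocorticoid-induced genes Ddit4 (−0.64 ± 0.19) and Dusp1 (−0.61 ± 0.19). In the cell cycle list 35 of 38 members were higher (score difference 0.28, camera adjusted p = 0.00166; adjusted p = 0.747 with an estimated correlation), with Racgap1 (0.60 ± 0.24), which acts in cytokinesis, and Mad2l1 (0.56 ± 0.23), which acts in the spindle checkpoint. No member of these 3 lists passed with limma, over all genes tested or adjusted over the list alone. At an unadjusted p under 0.05 there were 5, 3 and 4 members of the MHC class II, glucocorticoid and cell cycle lists, whose scores had exact p = 0.20, 0.0857 and 0.457. In the same order, 7, 3 and 23 of the 35 splits of the mice gave a camera p as small. The MHC class II list did not pass without female 3 (−0.13) or male 1 (−0.14), the glucocorticoid list without female 1 (−0.24) or female 3 (−0.16), and the cell cycle list without female 3 (0.01), male 1 (0.16) or male 2 (0.16).

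**Figure D3:**
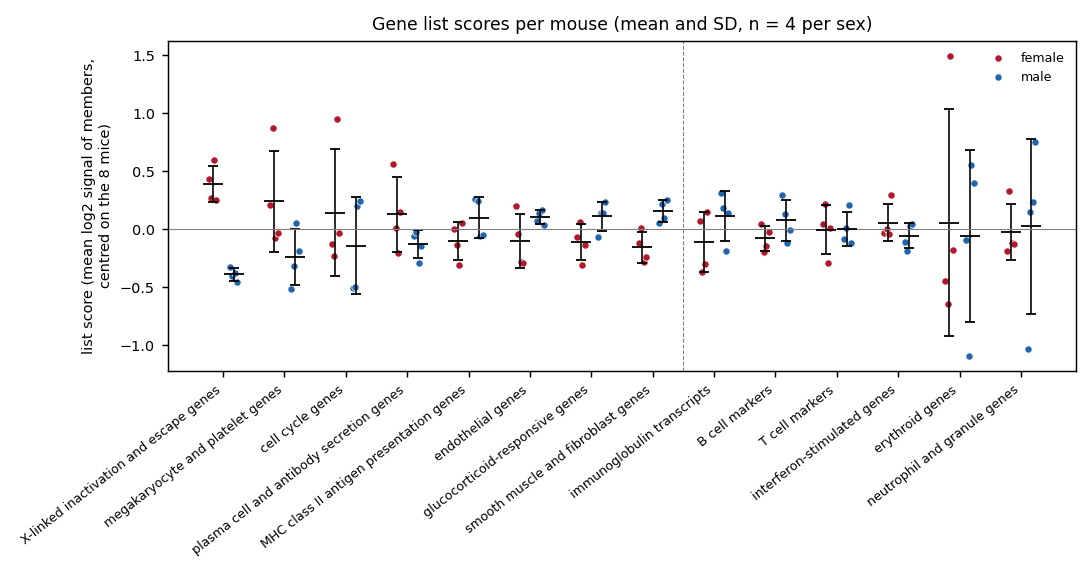
List score of each mouse, the mean log2 signal of the members centred on the 8 mice, for the 8 lists with a camera adjusted p under 0.05 (left of the dashed line) and 6 others (right), with bars for the mean and SD of 4 mice. The sexes separate fully in the X-linked list and in the smooth muscle and fibroblast list. In the erythroid list female 3 and male 2 (−1.09) lie far apart within a spread shared by both sexes.

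Lists tied to sex hormones, interferon and lupus did not pass in the reported setting. Estrogen-responsive genes had 11 of 16 members lower in females (camera adjusted p = 0.324), with Igf1, a growth factor, at 0.48 ± 0.17 and Cd22, an inhibitory receptor of B cells, at −0.63 ± 0.22. Androgen-responsive genes had 9 of 16 lower (adjusted p = 0.521), with Camkk2, a calmodulin-dependent kinase, at −0.49 ± 0.15 and Sat1, an enzyme of polyamine breakdown, at −0.34 ± 0.19. Sex steroid receptors and metabolism genes had 10 of 16 lower (adjusted p = 0.477), with Akr1c18, a progesterone-metabolising enzyme, at 0.57 ± 0.26 and the steroid receptor coactivator Ncoa1 at −0.30 ± 0.16. Interferon-stimulated genes had 25 of 39 members higher (adjusted p = 0.108), and lupus-locus and lupus-associated genes 15 of 24 (adjusted p = 0.593), with the complement gene C1qa at −0.26 ± 0.13 and the lymphocyte receptor gene Slamf6 at −0.31 ± 0.16. With limma 0 members of these 5 lists passed over all genes tested, and 5, 1, 1, 6 and 0 had an unadjusted p under 0.05. Adjusted over the list alone, only Isg15, an interferon-induced ubiquitin-like protein, passed (0.73 ± 0.17, adjusted p = 0.234 over all genes). The interferon-induced GTPase Igtp stood at 0.44 ± 0.16. The interferon list (score difference 0.11) passed in 3 of 14 alternatives (adjusted p from 0.00982 to 0.756): on chip A alone and without female 3 (0.14) or male 3 (0.14). Without female 4 or male 2 the difference was 0.03 or 0.07.

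Other cell types and immune functions did not pass as lists in the reported setting. NK cell and cytotoxic genes were lower in females in 12 of 13 members (score −0.23, camera adjusted p = 0.0561), with the pore-forming protein perforin (Prf1) at −0.75 ± 0.27 and granzyme A (Gzma) at −0.48 ± 0.18. The NK list passed in 5 of 14 alternatives (adjusted p from 0.00156 to 0.633): without the filter, on chip A alone, and without female 4 (−0.33), male 2 (−0.24) or male 4 (−0.26). T cell markers (−0.01, adjusted p = 0.857) held Cd28 at 0.47 ± 0.19 and Satb1 at −0.38 ± 0.16. Monocyte and macrophage markers (−0.07, adjusted p = 0.297) held the haem-degrading enzyme gene Hmox1 at 0.50 ± 0.14 and Aif1 at −0.49 ± 0.18. Dendritic cell markers (−0.10, adjusted p = 0.231) held the chemokine receptor gene Ccr7 at −0.42 ± 0.22 and the chemokine gene Ccl22 at 0.48 ± 0.26. Their difference ranged from −0.17 without male 4 to −0.05 on chip A alone. Neutrophil and granule genes (−0.05, adjusted p = 0.857) held the NADPH oxidase subunit Cybb at 0.46 ± 0.21 and Csf3r at 0.33 ± 0.27, with 1 of 3 Csf3r probe sets in that direction. Male 1 had the lowest neutrophil score (−1.03), and without it the difference was −0.41 and the list passed; without male 4, which had the highest (0.75), it turned to 0.19. Mast cell and basophil genes (−0.02, adjusted p = 0.857) held Kit at −0.23 ± 0.20 and Cma1 at 0.27 ± 0.23. Without the filter the mast cell difference was −0.22 (camera adjusted p = 0.169). Cytokines and chemokines (−0.06, adjusted p = 0.410) held Flt3l at −0.49 ± 0.17 and Il1a at 0.70 ± 0.29. MHC class I genes (−0.15, adjusted p = 0.194) held Tap1 at 0.32 ± 0.15 and B2m at −0.29 ± 0.16. Immediate early and heat shock genes (−0.11, adjusted p = 0.109) held Klf2 at −0.77 ± 0.25. In the complement list the score (0.01, adjusted p = 0.857) and the median of the members (−0.06) differed in sign. C1qb stood at −0.34 ± 0.18, with 1 of its 2 probe sets in that direction. With limma 0 members of these 10 lists passed over all genes tested or adjusted over the list alone. The unadjusted counts under 0.05 were 2, 2, 3, 0, 1, 0, 4, 0, 4 and 0 in the order given. Several of the small differences had no stable direction. That of T cell markers turned to 0.09 without female 3 and 0.06 without male 3, and also turned sign when arrays were scaled to the same median, without the filter and with the mean of all probe sets. Without female 3 those of monocyte and macrophage markers and of cytokines turned to 0.01 and 0.04, the latter also without the filter (0.02). The neutrophil difference also turned without female 1 or male 3, the mast cell one without female 1, male 3 or male 4, and the complement one without female 4 or male 4 and on chip A alone, to values between −0.05 and 0.04.

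Erythroid genes, an abundant group in mouse spleen, varied more within each sex than between the sexes. Their score was 0.06 ± 0.98 in females and −0.06 ± 0.74 in males (SD, n = 4 each; camera adjusted p = 0.480), with Nfe2 at 0.29 ± 0.23 and Gata1, a master regulator of the lineage, at 0.66 ± 0.55. The difference of 0.11 turned to −0.37 without female 3, where the list passed, and −0.23 without male 2, and it passed at 0.35 without female 2. Lists of neighbouring tissue gave pancreatic acinar genes 6 of 6 members higher in females (score 0.31, camera adjusted p = 0.109; Gp2 0.61 ± 0.35, Pla2g1b 0.30 ± 0.26) and adipocyte genes 3 of 6 (score 0.01 with a median of −0.01, adjusted p = 0.857; Scd1 −0.24 ± 0.21, Lep 0.26 ± 0.24). The adipocyte difference turned to −0.11 without female 2 and also turned without female 1 or male 3, without the filter and with the mean of all probe sets. The pancreatic list passed without female 1 (0.51) or male 3 (0.50), and its difference was 0.08 without female 4 or without the filter and 0.18 without male 4. In the erythroid, pancreatic and adipocyte lists 0 members passed with limma, 0 passed adjusted over the list alone and 0 had an unadjusted p under 0.05.

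Further genes with the smallest p in each direction did not pass but had no overlap between the sexes. Higher in females were Nepro on chromosome 16 (1.90 ± 0.37, adjusted p = 0.263), Sap130, a subunit of a histone deacetylase complex (1.35 ± 0.28, adjusted p = 0.370), the metallothionein gene Mt3 (1.11 ± 0.24, adjusted p = 0.202) and Diras2, a small GTPase gene (1.04 ± 0.23, adjusted p = 0.375). Lower in females were the matrix protein gene Svep1 (−1.08 ± 0.24), the antioxidant enzyme gene Gpx3 (−0.97 ± 0.21), Rcsd1 (−0.96 ± 0.20) and the sorting receptor gene Sorl1 (−0.76 ± 0.16), with adjusted p between 0.202 and 0.375. Only 2 of 3 probe sets of Sap130 and 1 of 2 of Gpx3 went in the stated direction. Of assignments of 8 mice to groups of 4, a share of 0.0286 gives no overlap for a given gene by chance.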

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

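The tests of explanations and the counts over other splits of the mice given here were chosen after the results were seen, except for the test of B cell markers against the immunoglobulin genes as a set and the test of X-linked genes in general.

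In 18 of 226 groups of 4 mice, a single mouse stood apart from the other 3, by a gap that took up most of the group's range; chance gives about 1 in 20, or 11.3 groups. Female 3 was such a mouse 5 times: it was highest in the cell cycle score (gap 0.834 of the range) and in Racgap1 (0.876), and lowest in Sat1 (0.958), Ncoa1 (0.919) and the dendritic cell score (0.880). Female 2 was highest in Gp9 (0.909), the neutrophil score (0.868) and Lep (0.832), and lowest in Akr1c18 (0.877). Female 4 was highest in Nono on chip A (0.876), in the interferon-stimulated score (0.893) and in Kdm5d (1.0, the other 3 females being at the floor). Female 1 was lowest in Pla2g1b (0.924). Among males, male 1 was highest in Ighg3 (0.878) and in the median signal of chip C (0.830, 232 against 213 to 216), male 2 lowest in Csf3r (0.917), male 3 highest in Cma1 (0.853) and male 4 highest in Kit (0.891).

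The 8 mice can be split into groups of 4 in 35 ways. On chip A the real split called 5 probe sets, 1 of the 35 splits (the real one) called as many, and the highest other called 3. That is the smallest share that 35 splits can give, for a count chosen after the results were seen. The 5 include Xist, which follows the sex of the mouse, and the count was 1 without the variance trend. Chance is therefore not excluded for the total of 5. Of the 5, 3 are X-linked (Xist, Kdm6a and Nono). The other 2 are fewer than the 3 calls of the highest other split, so that the count says nothing against chance for them. On chip B it called 2, 2 of 35 called as many and the highest other called 22; on chip C it called 1, 4 of 35 called as many and the highest other called 2. For the gene lists it called 8, 15 of 35 called as many and the highest other called 13. For these 3 counts, though the chip B calls include the Y-linked Kdm5d, which follows the sex of the mouse, chance cannot be excluded either. Nor can it for the counts at an unadjusted p under 0.05: 650, 577 and 360 on chips A, B and C were reached by 4, 4 and 6 of the 35 splits, with 903, 1103 and 445 as the highest others. For single lists, a camera p as small came from 23 of 35 splits for cell cycle, 9 for plasma cell and 7 for MHC class II genes. The counts were 5 for endothelial, 4 for megakaryocyte and 3 for glucocorticoid-responsive genes. For the smooth muscle and X-linked lists the count was 1. The chip B split with 22 calls, several times the real count, grouped female 1 with males 1, 2 and 3, which points to a structure of the samples besides sex.

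A kappa light chain variable segment was lower in females, and most immunoglobulin probe sets leaned the same way. For the kappa segment, the tests of fewer B cells or fewer antibody-secreting cells in females cannot decide. B cell markers differed by −0.16 and secretion genes by 0.26, much less than the segment. The segment stayed lower in females after either score was subtracted (−1.33 and −1.74, each with exact p = 0.0286). It was chosen for its difference between the sexes, so that this p follows largely from the choice. For the immunoglobulin genes as a set neither explanation is decided. The difference left after subtracting the B cell markers had exact p = 0.371. That after subtracting the secretion genes, themselves higher by 0.26, had exact p = 0.0857. A difference between the fluidics stations cannot be told apart from sex, as 0 arrays were washed on the station of the other sex. A difference between the sexes in which kappa segments are used may be the biology here, a hypothesis that signal per probe set alone does not test. Whether the probe sets of this segment also read related kappa segments was not tested.

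Without female 1, calls increased from 5 to 43 on chip A and from 2 to 29 on chip B. In 31 of these 43 and 24 of these 29, female 1 lay nearer the male mean than the mean of the other females. Most of these calls were gained by leaving female 1 out, so that its place follows largely from the choice. A fault of its chip A array alone is argued against, since its departures from the female mean were shared between chips A and B (r = 0.329 across 834 genes, which are not independent replicates, against at most 0.0717 between different mice of the same sex). A male sample under its label is argued against, as its Xist signal was 15.0 times that of the highest male. More degraded RNA stays open: female 1 had the highest ratio of 3′ to 5′ signal of the 8 mice in 0 of 6 comparisons, but on chip A the highest of the 4 females for Actb (1.10) and Gapdh (1.10). From the highest of the 8 mice, its rank was 3 (Actb) and 5 (Gapdh) on chip B, and 6 and 7 on chip C. A difference in the labelling reaction that fed its 3 arrays stays open and may act together with a biological difference of that mouse; no table here separates them.

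Nono and Kdm6a were higher in females by 0.98 to 1.66 on the log2 scale. A general rise of X-linked genes is argued against as the cause of differences of that size: the median of 292 X-linked genes exceeded that of 10051 autosomal genes by 0.0963. A strain variant under the probes stays open, because males carry the X chromosome of the maternal strain alone and the probe sets of each gene differed among themselves. For each gene 2 of 3 probe sets separated the sexes with no overlap, and the lowest difference was 0.24 for Nono and −0.01 for Kdm6a. Expression of these genes from both X chromosomes in females may contribute, as an untested hypothesis. The fluidics station stays open here as well, since it cannot be told apart from sex.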

How the results depend on the processing

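All alternatives given here were planned except the immunoglobulin list by symbol and its values without each mouse, which were chosen after the data were seen.

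For genes called, chip A, 5 in the reported setting, the count was 1 without the variance trend, 1 with the mouse number as a block, 1 with the unmoderated test, 2 with the fluidics module as a block and 2 with adjustment over the 3 chips; leaving out each mouse gave 1 to 43. For genes called, chip B, 2 as reported, it was 0 with the filter at the 75th percentile, which removes both called probe sets (337 at an unadjusted p under 0.05 with limma), 1 with the unmoderated test and 2 with the block, and leaving out each mouse gave 2 to 29. For genes called, chip C, 1 as reported, it was 0 without the trend (340 unadjusted, limma), 0 with the unmoderated test (323 unadjusted) and 1 with the block, and leaving out each mouse gave 1 to 2. The cause was not tested except where stated. Mouse numbers do not pair the sexes, so the block is given only as a check.

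Of the gene lists, 8 passed as reported and 8 with the block, 0 with an estimated correlation (2 unadjusted) and 6 to 12 without each mouse. The erythroid list, not called at 0.11, ranged from −0.37 without female 3, where it passed in the other direction, to 0.35; the cause was not tested. With every immunoglobulin gene taken by symbol the list passed with the preset correlation and not with an estimated one, at a score difference of −0.41, and −0.26 without female 1, with 31 in place of 35 of 49 probe sets lower. Quantile scaling left 5, 2 and 1 calls, the same probe sets, and 8 lists. Signals near the floor limit what can be seen of dim genes, and chip C, with the largest residual SD (0.47), recovered the fewest simulated changes.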

Other observations

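The tests given here were chosen after the results were seen, except the difference of medians between X-linked and autosomal genes.

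Individual females each had immunoglobulin probe sets far from every other mouse. An immunoglobulin kappa probe set read 8506 in female 1 against 88.1 to 195 in the other mice. An Ighg3 probe set read 24004 in female 4 against 1521 to 5042, and other Ighg3 probe sets read 13168 and 9639 in female 2 against at most 5176 and 3925. A kappa variable probe set read 20632 in female 3 against 2532 to 9269. A lambda variable gene, Iglv1, read 227130 in female 4 against 39209 to 87793. The mouse farthest from the median was a female for 41 of 49 immunoglobulin probe sets, 25 of them in female 1. It was a female for 857 of 1172 other chip A probe sets of that signal level. The exact test compared the counts per mouse between females and males, and gave p = 0.0286 for each set. It does not test the share of female 1. The wider spread among females was therefore not limited to immunoglobulin genes. In a separate comparison of spreads, the SD among females over that among males exceeded its value in those other probe sets by 0.55 (difference of median log2 ratios) for 47 chip A immunoglobulin probe sets, and 26 of the 35 splits of the mice gave a difference as large.

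Erythroid and cell cycle genes varied together over the 8 mice, without a shared gene between the lists. Pearson's r was 0.908 (exact permutation p = 0.00268, adjusted p = 0.0723 over 27 relations) and Spearman's rho 0.738 (exact permutation p = 0.0458, adjusted p = 0.518), so that neither passed the adjustment. Without female 3 and male 2, the mice farthest from the median erythroid score, r was 0.665. Groups of 4 mice washed on one station are too few for a relation within each.

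X-linked genes as a whole lay slightly higher in females. Of 292 genes, 27 were higher and 5 lower at an unadjusted p under 0.05, against 403 and 526 of 10051 autosomal genes. The difference of medians was 0.0963, and 1 of 35 splits, the real one, gave a difference as large (highest other 0.0944).

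Female arrays resembled each other less than male arrays did on chips A and B. The mean correlation of an array with the other arrays of its sex was 0.919 to 0.942 in females and 0.956 to 0.960 in males on chip A, and 0.862 to 0.883 and 0.910 to 0.915 on chip B. On chip C the ranges overlapped, 0.810 to 0.823 in females and 0.821 to 0.832 in males.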
